A study of Homo sapiens with 12 samples.

How the data were processed

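The libraries came from PLC/PRF/5, a human hepatoma cell line. The design names 3 groups: control cells, cells in which HKDC1 was knocked out (KO) and knockout cells in which HKDC1 was put back (KO_RES, called rescue here). HKDC1 encodes a hexokinase domain protein, a relative of the enzymes that phosphorylate glucose. Each group had 4 libraries. The knockout and rescue libraries came from 2 lines, KO1 and KO2, with 2 libraries each per group, and are named by line and number (KO 1_2 is line 1, number 2). The labels do not say whether the lines are single-cell clones or guides, whether libraries came from separate cultures, or at which oxygen level the cells were grown, although the series title names hypoxia. The p-values therefore measure only the spread between these samples, which may be technical.

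The deposited files held raw counts of reads per gene for each library, made by the authors with STAR 2.6.0b on the GRCh37 build, as the submitters' processing notes name them, from a stranded mRNA library kit. Each file listed 57820 Ensembl gene identifiers in unstranded and stranded columns after 4 lines of unassigned reads, which were left out of every test. Trimming and filters were not stated. Column 4 was used, since its total was between 19.8 and 21.1 times that of the other strand in every library. Gene symbols were taken by identifier first from a reference list of gene names, which named 39538 genes. Remaining identifiers were looked up in GENCODE release 29, which is built on GRCh38, and 40357 genes had a symbol in the end. Chromosomes came from GENCODE release 29. Coordinates are not given, since the builds differ. Genes without a symbol held 5.61% of the counts.

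Groups followed the sample titles. The genotype field gives another group than the title for 4 libraries (KO 1_2, KO 2_2, KO_RES 1_1 and KO_RES 2_1) and agrees for 8, so fits by the genotype field, and fits with only the 8, were run as alternatives. Among knockout and rescue libraries the genotype field divides the samples exactly by their number, with number 1 as KO and number 2 as KO_RES.

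Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr, library sizes were scaled by TMM, and groups were compared with quasi-likelihood tests. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. A fit of 3 groups tested 19200 genes with a common biological coefficient of variation of 36.2%. A fit of 5 groups (control, KO1, KO2 and the rescue of each) tested 20559 genes at 25.8%. For rescue against knockout, fits with the line as a block, or with line and number as a pair block over 8 libraries (18293 genes, 13.9%), were alternatives. Levels are CPM, read counts scaled to library size with TMM factors, and are given as mean ± SD over n = 4 libraries. Means of a line rest on 2 libraries and are given without an error. A value from 0 to 3 counts is read as at the floor, between 0.0418 and 0.0832 CPM by library. This floor covers counting error only, because reads without molecular identifiers are not independent molecules.

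The 27 gene lists covered glycolysis, hypoxia response genes outside glycolysis, Wnt/beta-catenin targets, liver cancer stem cell markers, hepatocyte function, the nuclear-encoded respiratory chain, mitochondrially encoded genes, the cell cycle, cholesterol synthesis, fatty acid synthesis and storage, fatty acid oxidation, the pentose phosphate and hexosamine pathways, the ATF4 stress response, endoplasmic reticulum chaperones, mesenchymal and epithelial markers, interferon-stimulated genes, NF-kB, p53, NRF2 and YAP/TAZ targets, heat shock genes, lysosome and mitophagy genes, replication-dependent histones, and markers of fibroblasts, blood cells and endothelium. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and fry were alternatives.

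The groups, tests, lists and the following rule for named genes were chosen before the data were examined. For each of KO against control and rescue against KO, the rule took the 12 largest rises and the 12 largest falls among called genes with a symbol, a mean of at least 2 CPM and groups that did not overlap. It also took up to 4 called members per list with the smallest adjusted p, the 5 largest differences each way between the KO lines, genes changed by knockout and changed back by rescue, the hexokinases and CTNNB1. Other genes named in the text were chosen after their values were seen.

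The remaining alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, unstranded counts, fits of only the groups compared, a fold threshold of 1 on the log2 scale, the mean of both lines in the 5-group fit, and leaving out each library in turn. Added after the data were seen were leaving out controls 1 and 2, leaving out controls 3 and 4, the pair block without the 2_2 pair, DESeq2 with the pair block, and a fit of the difference between libraries numbered 2 and 1. The fits were tested on simulated data with 200 changed genes. At a 4-fold change 77.3% of the changed genes were recovered for KO against control, 57.6% for rescue against KO and 98.5% under the pair block. At a 2-fold change 28.4%, 20.9% and 65.7% were recovered. False calls were 6.4%, 1.9% and 6.9% of calls. The simulations for the 3-group fit drew libraries independently, without the control pairs and lines that stand apart in the data. Their recovery and false-call shares therefore need not hold for the real tests.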

Results

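RNA was sequenced from 12 libraries of PLC/PRF/5 hepatoma cells: 4 control, 4 HKDC1 knockout (KO) and 4 rescue (KO_RES) libraries. The knockout and rescue libraries came from 2 lines, KO1 and KO2, with 2 libraries per line and group. Counts over genes ran from 57333288 to 71853616 in the controls, from 42609910 to 68040103 in KO and from 36075411 to 60154638 in KO_RES. The design asks how losing and restoring HKDC1 changes expression in liver cancer cells, and the series title names stemness, hypoxia and beta-catenin. Controls 1 and 2 stood far apart from controls 3 and 4: albumin (ALB) was at 908 and 822 CPM in controls 1 and 2 and at 23.0 and 28.2 CPM in controls 3 and 4. For KO against control, the count of genes and most gene lists past the threshold are therefore also described against a single pair of controls.

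HKDC1 itself was lower than control in line KO2, not in line KO1, and far above control in the rescue of both lines. HKDC1 (ENSG00000156510.11, chromosome 10) was at 156.8, 154.4, 182.9 and 123.5 CPM in controls 1 to 4. It was at 153.0 and 146.7 CPM in the KO1 libraries and at 91.2 and 49.3 CPM in the KO2 libraries. The rescue libraries were at 1237 and 1546 CPM in line 1 and at 507 and 626 CPM in line 2, which is 9.29 and 8.07 times the mean of their knockout line and 9.01 and 3.67 times the control mean. In the 5-group edgeR fit the log2 fold change against control was -0.05 for KO1 (adjusted p = 0.92) and -1.14 for KO2 (adjusted p = 0.0161), and the lines differed by -1.09 (KO2 minus KO1, adjusted p = 0.0269).

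Over both lines, HKDC1 was at 154 ± 24.3 CPM in control and 110 ± 49.1 CPM in KO (SD, n = 4 each), with a log2 fold change of -0.49 (SE 0.39, adjusted p = 0.51). For rescue against KO it was 3.15 (SE 0.42), all 4 rescue libraries being above all 4 knockouts. That change missed the threshold in the 3-group edgeR fit (adjusted p = 0.156). It passed without the filter on low counts (3.15, adjusted p = 0.0158), with DESeq2 (3.15, adjusted p = 1.7e-10), with line and number as a pair block (3.15, adjusted p = 0.00347) and with the line as a block (3.12, adjusted p = 0.00144). The mRNA level thus follows the titles of the rescue libraries, and not the genotype field, while the knockout label of KO1 cannot be checked from mRNA. The labels name neither the edit nor its place.

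**Figure D1:**
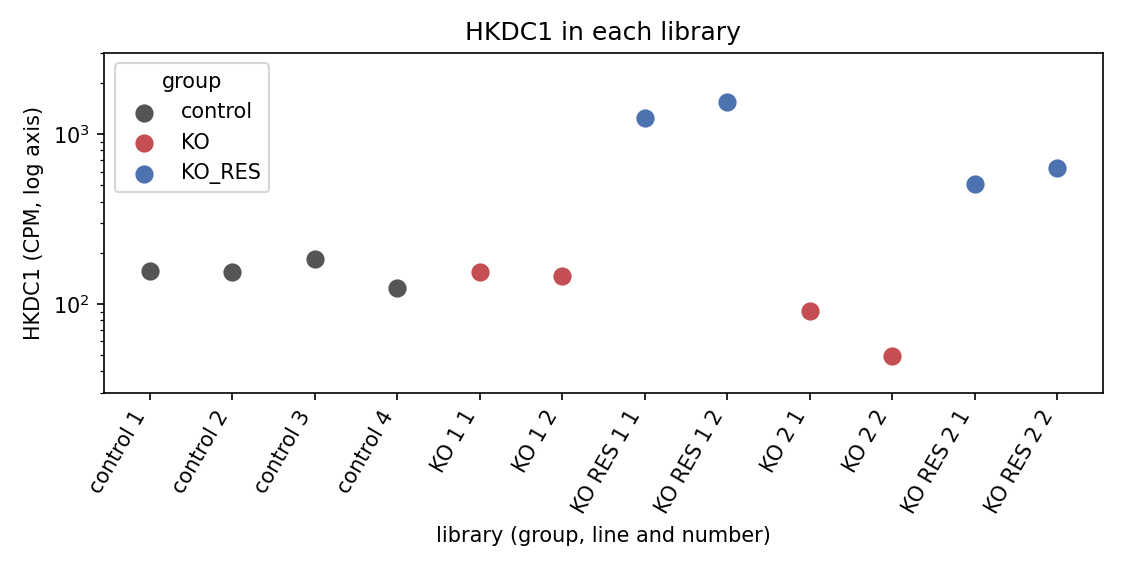
HKDC1 level in CPM (log axis) in each of the 12 libraries, with 1 point per library, coloured by group. The 4 rescue libraries sit between 507 and 1546 CPM, above all others, and the KO1 libraries lie within the range of the controls.

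HK1 passed no test between groups, and whether HK2 passed depended on the fit. HK2, the hexokinase typical of hepatoma cells, was at 9.5 ± 1.92 CPM in control, 26.5 ± 10.5 in KO and 13.7 ± 9.16 in KO_RES. Its log2 fold change for KO against control was 1.48 (adjusted p = 0.085) in the 3-group fit. HK2 for KO against control passed in 4 of 22 alternatives: with DESeq2, with only the groups compared, without KO_RES 1_1, and as the mean of the lines in the 5-group fit (1.42, adjusted p = 0.00336). It rose in each line in the 5-group fit (KO1 1.0, adjusted p = 0.0316; KO2 1.83, adjusted p = 0.0027). For rescue against KO, HK2 had a log2 fold change of -0.95 (adjusted p = 1), or -1.15 under the pair block (adjusted p = 0.134), with each rescue library below its pair. Of 25 alternatives for HK2 in rescue against KO, 1 passed, DESeq2 with the pair block (-1.17, adjusted p = 1.49e-05). HK1 had means of 22.5, 24.6 and 24.0 CPM in control, KO and KO_RES (0.13 for KO against control, adjusted p = 0.715). HK3 averaged at most 0.0738 CPM in a group, at the level of the floor. CTNNB1, which encodes beta-catenin, was at 508 ± 37.3, 368 ± 119 and 288 ± 117 CPM. It did not pass the test for KO against control (-0.47, adjusted p = 0.337), and in the 5-group fit it fell in KO1 (-0.92, adjusted p = 0.017) and did not pass in KO2 (-0.12, adjusted p = 0.783). The lines' difference in CTNNB1 did not pass either (0.80, adjusted p = 0.0634).

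Knockout against control asks how the 2 knockout lines differ from control, although HKDC1 mRNA was at 0.97 times the control mean in KO1 and 0.45 times in KO2. The desmosomal cadherin DSC2 went from 46.1 ± 25.1 CPM in control to 0.0751 ± 0.0517 CPM in KO, which is near the floor (adjusted p = 4.25e-05). LIMCH1, a regulator of myosin and cell adhesion, went from 41.1 ± 2.50 to 1.57 ± 0.786 CPM (log2 -4.72, SE 0.43, adjusted p = 0.000313). The calcium channel subunit CACNA2D1 went from 31.7 ± 4.29 to 0.360 ± 0.173 CPM (adjusted p = 0.0012), and the protease inhibitor TFPI2 from 31.8 ± 4.0 to 0.815 ± 0.473 CPM (adjusted p = 0.000946). Among rises, DPYD, which starts pyrimidine breakdown, went from 0.363 ± 0.0605 to 16.4 ± 9.30 CPM (log2 5.49, SE 0.63, adjusted p = 0.00102). The cytokine IL17D went from 0.308 ± 0.151 to 8.81 ± 4.03 CPM (4.82, SE 0.52, adjusted p = 0.000717) and the zinc finger factor ZBTB16 from 0.129 ± 0.0911 to 2.72 ± 0.397 CPM (4.38, SE 0.45, adjusted p = 0.000638).

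The organic anion transporter SLC22A8 also fell, from 7.35 ± 2.55 to 0.0532 ± 0.0227 CPM (adjusted p = 0.000713), near the floor. With DSC2, LIMCH1, CACNA2D1, TFPI2, DPYD, IL17D and ZBTB16 it kept its call in every alternative run for KO against control, including against either pair of controls. The other large falls named by the rule were DSC3, CD36, ABCA8, VCAM1, GC, MASP1 and TTR, and the other large rises were PAGE5, ARMCX1, PASD1, DIO3, CTTNBP2, CFTR, MGAM, ZNF860 and RPS6KA2. CFTR, a chloride channel, was at 4.18 ± 2.74 CPM in control and 160 ± 158 CPM in KO (5.26, SE 1.23, adjusted p = 0.0285). It lost its call against either pair alone (4.66, adjusted p = 0.22 with controls 3 and 4; 6.29, adjusted p = 0.073 with controls 1 and 2). Several of these depended on the controls. CD36, a fatty acid carrier, fell by 8.36 on the log2 scale against controls 1 and 2 (adjusted p = 0.00021) and had -1.64 against controls 3 and 4 (adjusted p = 0.40). TTR, a thyroxine carrier made by the liver, had -6.07 (adjusted p = 0.0086) and -2.10 (adjusted p = 0.41).

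In all, 1206 of 19200 genes were called for KO against control, 551 higher and 655 lower in KO. At least a doubling or halving was fitted for 287 of the higher and 264 of the lower genes. With controls 3 and 4 only, 337 genes were called, and 233 of the 1203 main calls tested in each fit were called again; with controls 1 and 2 only, 749 were. Of the 1203, 188 were called against both pairs, and 7 genes were called against both pairs with opposite signs. The count was 525 without control 1, 509 without control 2, 591 without KO 1_1, 562 without KO 1_2 and 651 without KO 2_1, and it was 72 with only the libraries whose title and genotype field agree. Of the 69 genes named for this comparison, 26 kept their call whichever single library was left out and 43 lost it in at least 1 case. Against controls 3 and 4 only, 17 of the 69 kept their call, and against controls 1 and 2 only, 53 did. Those that kept it against each pair were DPYD, IL17D, ZBTB16, DSC2, DSC3, SLC22A8, ABCA8, CACNA2D1, VCAM1, TFPI2, LIMCH1, TBX3, EPCAM and TM7SF2, so every other gene of the 69 lost its call against at least 1 pair.

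**Figure D2:**
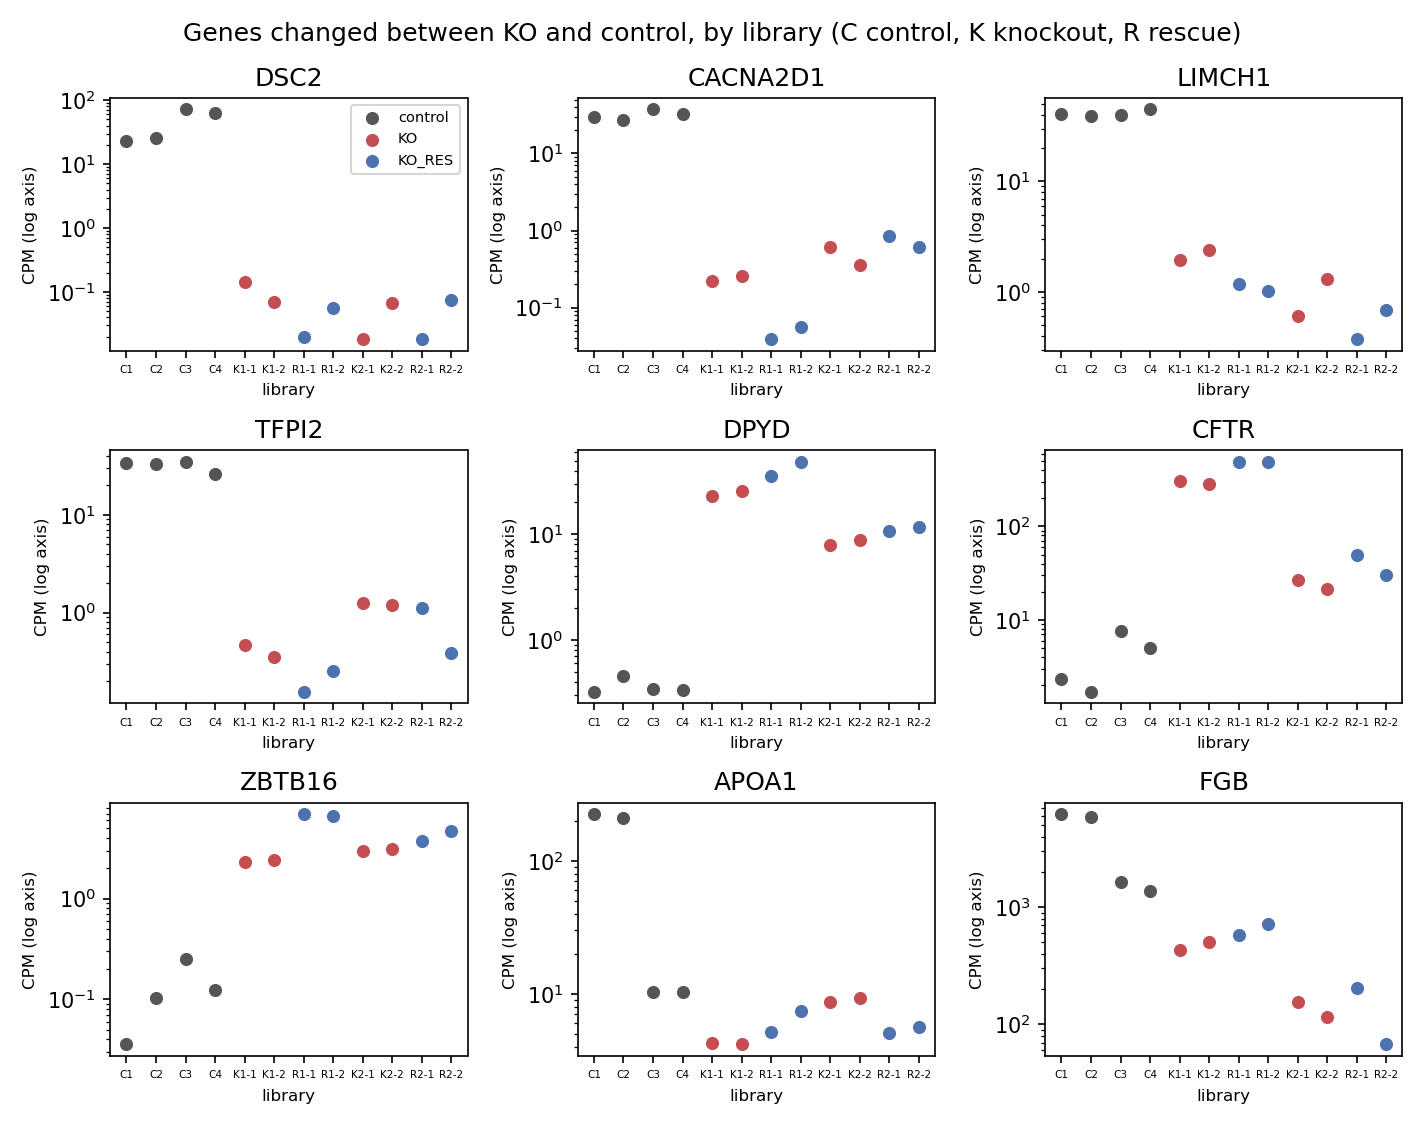
Level in CPM (log axis) of 9 genes called between control and KO, a panel each, with a point per library of the control, KO and KO_RES groups. DSC2 lies near the floor in every KO and KO_RES library, while DPYD is between 0.323 and 0.453 CPM in the controls.

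Genes of the integrated stress response that ATF4 directs were higher in KO, and chaperones of the endoplasmic reticulum were lower. Of 20 tested stress response genes all had positive fold changes, and 5 rose (6 adjusted over the list alone). In the 5-group fit the median of this list was 0.68 in KO1, with 6 rises, and 0.46 in KO2, with 1. The chaperone medians there were -0.49 and -0.63. The asparagine synthetase ASNS went from 205 ± 43.8 to 383 ± 44.0 CPM (0.91, adjusted p = 0.0397), SESN2 had a log2 fold change of 1.47 (adjusted p = 0.0284), TRIB3 2.19 (adjusted p = 0.0441) and VLDLR 1.69 (adjusted p = 0.0199). Of 16 chaperone genes 6 fell (11 adjusted over the list alone), among them HSP90B1 (2250 ± 269 to 1206 ± 119 CPM, -0.90, adjusted p = 0.00445), PDIA6 (-0.83, adjusted p = 0.00706), CRELD2 (-0.85, adjusted p = 0.0102) and SDF2L1 (-0.71, adjusted p = 0.0162). Camera gave an adjusted p of 2.5e-08 for each list, with median log2 fold changes of 0.60 and -0.53. With an estimated correlation the adjusted p was 0.49 for each, and none of the 13 lists past the threshold kept its call. At the preset correlation these lists passed against controls 3 and 4 alone (0.70, adjusted p = 2.2e-08; -0.32, adjusted p = 0.00096) and against controls 1 and 2 alone (0.55, adjusted p = 1.8e-05; -0.71, adjusted p = 5.7e-11). All 8 genes named here lost their call against controls 3 and 4 alone, with adjusted p-values from 0.052 (HSP90B1) to 0.17 (SESN2 and SDF2L1). ASNS (0.73, adjusted p = 0.16) and VLDLR (1.73, adjusted p = 0.065) also lost it against controls 1 and 2 alone. Between knockout and rescue libraries numbered 2 and 1, the stress response list differed by a median of 0.54 with 14 genes called. That is close to its 0.60 for KO against control, while the chaperone list differed by -0.08.

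Genes of hepatocyte function, hypoxia response genes, mitochondrially encoded genes and cholesterol synthesis genes were lower in KO than in the 4 controls together, and none of these lists passed against controls 3 and 4 alone. Of 23 hepatocyte genes 8 fell (12 adjusted over the list alone), with a median of -1.46 (camera adjusted p = 1.8e-07, and 0.49 with an estimated correlation). Fibrinogen FGB went from 3766 ± 2614 to 303 ± 196 CPM (adjusted p = 0.0253), apolipoprotein APOA1 from 114 ± 120 to 6.60 ± 2.74 CPM (adjusted p = 0.026), and TDO2 went from 1.29 ± 1.02 to 0.0541 ± 0.0541 CPM. These 3 lost their call against controls 3 and 4 alone, where the adjusted p was 0.20 for FGB (-2.31), 0.42 for APOA1 (-0.65) and 0.16 for TDO2 (-2.84). Against controls 3 and 4 alone the hepatocyte median was -0.32 (adjusted p = 0.31), against controls 1 and 2 alone -2.16 (adjusted p = 4.3e-27). Of 22 hypoxia response genes outside glycolysis 5 fell (7 adjusted over the list alone): BNIP3 (92.6 ± 25.1 to 48.6 ± 6.16 CPM, -0.93, adjusted p = 0.0107), P4HA1 (-1.09, adjusted p = 0.0166), ERO1A (-0.44, adjusted p = 0.0338), ANGPTL4 (-0.92, adjusted p = 0.0447) and P4HA2. Against controls 3 and 4 alone BNIP3 (adjusted p = 0.075), P4HA1 (0.15), ERO1A (0.17) and ANGPTL4 (0.42) lost their call, and ERO1A lost it against controls 1 and 2 alone as well (0.064). The list median was -0.73 (camera adjusted p = 6.6e-05, and 0.49 with an estimated correlation), -0.09 against controls 3 and 4 alone (adjusted p = 0.087) and -0.89 against controls 1 and 2 alone (adjusted p = 2.4e-07).

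All 13 mitochondrially encoded genes had negative fold changes (median -0.80, camera adjusted p = 8.2e-07, and 0.51 with an estimated correlation). Of these MT-ND3 (-0.75, adjusted p = 0.0439) and MT-ATP6 (-0.92, adjusted p = 0.0466) fell, and 12 fell adjusted over the list alone. Against controls 3 and 4 alone the median was -0.23 (adjusted p = 0.17), and against controls 1 and 2 alone -1.20 (adjusted p = 8.1e-21). Cholesterol synthesis had 4 falls among 22 genes (7 adjusted over the list alone): TM7SF2 (-1.06, adjusted p = 0.00227), DHCR7 (-0.51, adjusted p = 0.0321), MSMO1 (-0.95, adjusted p = 0.0408) and FDPS (-0.86, adjusted p = 0.0434). Its median of -0.36 (camera adjusted p = 0.001, and 0.53 with an estimated correlation) was 0.02 against controls 3 and 4 alone (adjusted p = 0.60) and -0.64 against controls 1 and 2 alone (adjusted p = 2.2e-09).

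Wnt/beta-catenin targets were lower in KO, with 2 falls among 17 genes (3 adjusted over the list alone). TBX3, a transcription factor, went from 96.6 ± 62.3 to 13.0 ± 5.06 CPM (-2.89, SE 0.45, adjusted p = 0.00447), and ZNRF3, a Wnt receptor antagonist, had -0.64 (adjusted p = 0.0165) but passed against neither pair of controls alone (0.078 with controls 3 and 4, 0.062 with controls 1 and 2). The list median was -0.32 (camera adjusted p = 0.017, and 0.49 with an estimated correlation), -0.37 against controls 3 and 4 alone (adjusted p = 0.056) and -0.15 against controls 1 and 2 alone (adjusted p = 0.018). In the 5-group fit it was -0.50 in KO1 and -0.13 in KO2. Liver cancer stem cell markers went both ways: of 17 genes 2 rose and 4 fell (3 and 4 adjusted over the list alone; median -0.03, camera adjusted p = 0.93). EPCAM rose from 2.81 ± 1.61 to 26.7 ± 11.7 CPM (3.25, SE 0.59, adjusted p = 0.00887) and THY1 from 0.189 ± 0.0593 to 1.13 ± 0.410 CPM (2.57, adjusted p = 0.00412). CD47, a signal against phagocytosis, fell from 44.9 ± 6.30 to 18.2 ± 6.26 CPM (-1.30, adjusted p = 0.0248), and SOX2 from 1.13 ± 0.697 to 0.0613 ± 0.0590 CPM (adjusted p = 0.0179). CD47 (adjusted p = 0.17) and THY1 (0.06) lost their call against controls 3 and 4 alone, and SOX2 against controls 1 and 2 alone (0.078).

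Interferon-stimulated genes were higher, with 3 rises among 17 (4 adjusted over the list alone), among them USP18 (1.48, adjusted p = 0.0164) and ISG15 (1.09, adjusted p = 0.0408). Camera gave 0.0068 for that list (median 0.46, and 0.53 with an estimated correlation). NRF2 targets had 2 rises and 1 fall among 15, the same adjusted over the list alone. These were HMOX1 (88.0 ± 8.96 to 219 ± 50.8 CPM, 1.31, adjusted p = 0.00499), FTH1 (1.09, adjusted p = 0.0189) and AKR1B10 (-2.20, adjusted p = 0.0405), at a camera adjusted p of 0.044 (median 0.22, and 0.53 with an estimated correlation). Fatty acid synthesis and storage had 1 fall among 15 (2 adjusted over the list alone), the triglyceride enzyme DGAT1 (-0.78, adjusted p = 0.00595; list median -0.18, camera adjusted p = 0.049, and 0.49 with an estimated correlation). NF-kB targets (median 0.59, camera adjusted p = 0.038, and 0.70 with an estimated correlation), cell cycle genes (-0.19, 0.032 and 0.88) and replication-dependent histones (-0.51, 0.0054 and 0.63) passed without a called member. Histone transcripts of this kind lack poly(A) tails, so the list served as a check of how mRNA was selected. All 9 tested members were lower in KO, and no test separated a difference in RNA or library selection from the groups. Of these 6 lists, only the cell cycle (-0.29, adjusted p = 0.0016) and histone lists (-0.67, adjusted p = 0.0016) passed against controls 3 and 4 alone, and these 2 missed against controls 1 and 2 alone (-0.05, adjusted p = 0.70; -0.35, adjusted p = 0.26). NF-kB targets had a median of 0.06 against controls 3 and 4 alone (adjusted p = 0.87) and 1.14 against controls 1 and 2 alone (adjusted p = 9.4e-06). Interferon-stimulated genes had 0.44 (adjusted p = 0.15) and 0.67 (adjusted p = 0.0061), and fatty acid synthesis -0.05 (adjusted p = 0.66) and -0.24 (adjusted p = 0.025). NRF2 targets passed against neither controls 3 and 4 (0.26, adjusted p = 0.15) nor controls 1 and 2 (0.34, adjusted p = 0.19). In the 5-group fit, medians in KO1 and KO2 were 0.24 and 0.73 for interferon-stimulated genes, 0.56 and 0.02 for NRF2 targets. They were -0.34 and -0.34 for fatty acid synthesis, 0.92 and 0.23 for NF-kB, -0.44 and -0.02 for the cell cycle and -0.59 and -0.38 for histones. The NRF2, NF-kB and cell cycle shifts were thus mainly those of KO1, the line with HKDC1 at the control level.

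The remaining lists did not pass for KO against control. Glycolysis had 1 rise, PFKP (1.30, adjusted p = 0.0106), and 1 fall, PFKL (-0.71, adjusted p = 0.0116), among 23 genes (camera adjusted p = 0.51). Fatty acid oxidation had 2 falls, ETFB (-0.66, adjusted p = 0.027) and ACADVL (-0.69, adjusted p = 0.0353), among 16 (0.91). Of 14 pentose phosphate and hexosamine genes OGT rose (0.90, adjusted p = 0.00676) and UAP1 fell (-0.58, adjusted p = 0.034; list 0.91). Single falls were COX6C in the nuclear-encoded respiratory chain (-0.57, adjusted p = 0.0402; list 0.42), CDH1, or E-cadherin, among epithelial markers (-1.34, adjusted p = 0.0421; list 0.91), AXL among YAP/TAZ targets (-1.34, adjusted p = 0.0447; list 0.55) and BAG3 among heat shock genes (-0.73, adjusted p = 0.00705; list 0.68). Mesenchymal markers (0.84), p53 targets (0.86), lysosome and mitophagy genes (0.43), and fibroblast (0.91) and blood cell markers (0.91) had no called member. With 2 endothelial markers tested, that list had no test.

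**Figure D3:**
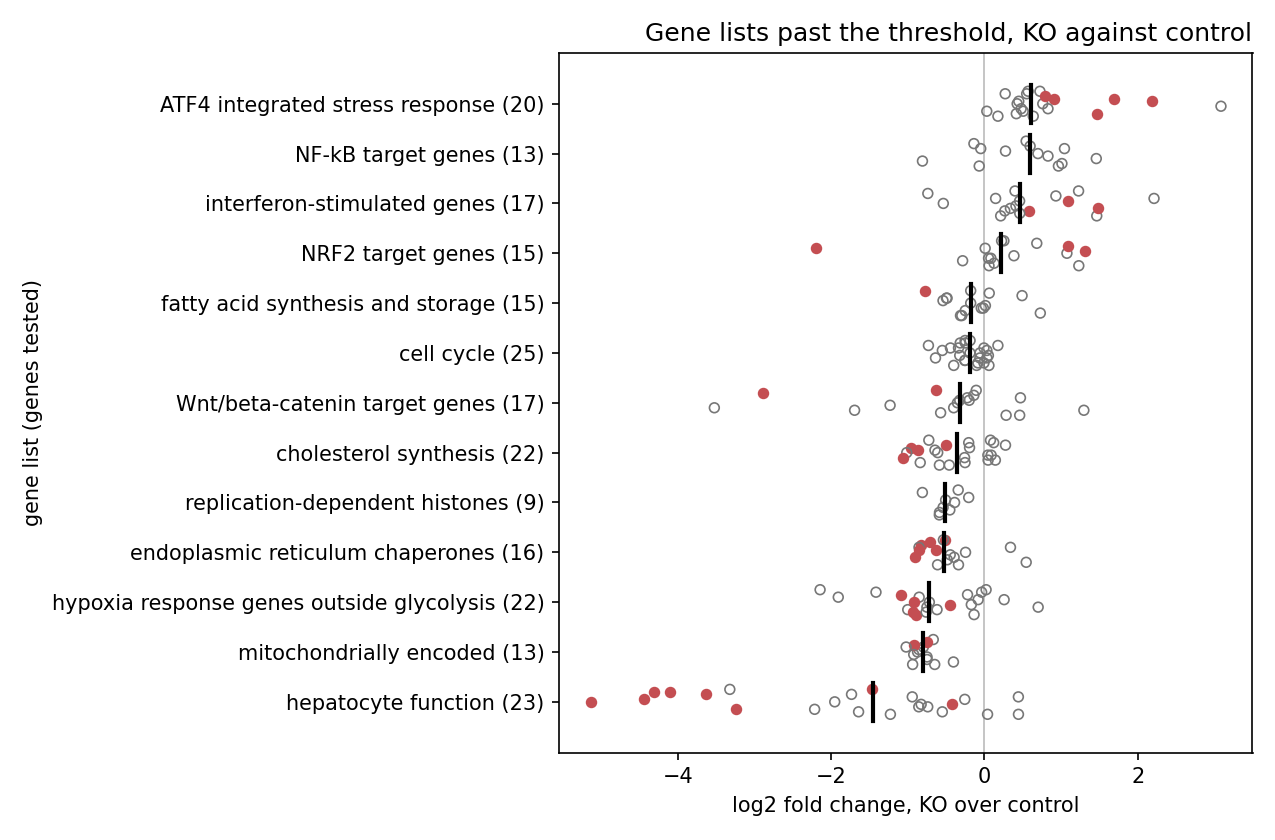
Log2 fold change of KO against control for each tested member of the gene lists past the threshold, with filled points for called genes, open points for the others and a black bar at each list's median. All 20 stress response genes lie to the right of 0 and all 13 mitochondrially encoded genes to its left.

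Rescue against KO asks which changes follow HKDC1 when it is put back. The pair block fit called 8 genes, 5 higher and 3 lower in rescue, whose names were chosen after their values were seen. After HKDC1 they were the oncofetal proteoglycan GPC3 (1.07, adjusted p = 0.00589), the retinol carrier RBP4 (1.09, adjusted p = 0.0222), CFTR (0.71, adjusted p = 0.0461) and ENSG00000117289.7 (2.29, adjusted p = 0.00589) as rises. The falls were the cancer-testis antigen MAGEC2 (-1.27, adjusted p = 0.016), the ubiquitin hydrolase UCHL1 (-1.17, adjusted p = 0.016) and the glutamate transporter SLC1A3 (-0.95, adjusted p = 0.0222). GPC3 rose from between 54.9 and 104.6 CPM in KO to between 103.5 and 228.8 CPM in rescue, in 4 of 4 pairs. A change in rescue need not be a return toward control. CFTR had 5.26 for KO against control and 5.98 for rescue against control in the 3-group fit, so rescue moved it further away. ENSG00000117289.7 moved back, with -3.03 for KO against control in DESeq2.

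The 3-group edgeR fit called 0 of 19200 genes for rescue against KO, with 473 at an unadjusted p under 0.05. DESeq2 called 5 (among them HKDC1, ENSG00000117289.7, AGR2 and SYT13), the line block 3 (HKDC1, UCHL1 and MAGEC2), and the pair block without the 2_2 pair 61. DESeq2 with the pair block called 473, and an edgeR fit with the number beside line and group called 531 (158 higher, 373 lower); these fits and the one without the 2_2 pair were chosen after the data were seen. Within lines, the 5-group fit called 40 genes in line 1 (8 higher, 32 lower) and in line 2 HKDC1 alone. In line 1 the cadherin CDH17 fell from 20.3 and 16.7 CPM to 1.09 and 0.425 CPM (-4.56, adjusted p = 0.00113), and AGR2, SYT13 and NTN4 fell as well (-2.13, -4.23 and -4.02), all chosen after their values were seen. The test of a different rescue effect in the lines called 0 genes with edgeR, 598 at an unadjusted p under 0.05; no other tool was run. It called 98 genes with the number as a block and 192 without the filter on low counts. It called 1, CDH17, without KO_RES 1_1 or without KO_RES 1_2.

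NRF2 targets were lower in rescue than in KO, all 15 with negative fold changes (median -0.38, camera adjusted p = 3.9e-09, and 0.13 with an estimated correlation). All 13 NF-kB targets were negative too (-0.44, 0.00012 and 0.47). No member of any list was called for this comparison over all genes. Adjusted over the list alone, 1 stem cell marker was higher, 2 mesenchymal markers and 1 YAP/TAZ target were lower, and no others were called. Camera also passed glycolysis (median -0.08, adjusted p = 0.019), stress response (-0.16, 0.015), interferon-stimulated (-0.17, 0.019), lysosome (-0.18, 0.015) and blood cell genes (-0.69, 0.015), the last a list of 3 genes with LYZ, and cholesterol synthesis upward (0.14, 0.028). With an estimated correlation these had adjusted p-values of 0.15, 0.70, 0.66, 0.19, 0.19 and 0.73. The count of 8 lists became 2 without KO 1_2, 4 without KO_RES 2_1 and 11 under the pair block. The stem cell markers (0.20), Wnt targets (0.58) and hypoxia response genes (0.61) did not pass.

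The rescue libraries also differed from control, which asks what stays unlike control when HKDC1 is put back. Against control, 1050 genes were called in rescue, 418 higher and 632 lower. Of these 786 were also called for KO against control, all in the same direction (321 up, 465 down), where 12 and 21.6 would be shared by independent draws. DSC2 was at 0.0422 ± 0.0276 CPM in rescue, DPYD at 26.6 ± 18.5 CPM and LIMCH1 at 0.816 ± 0.363 CPM. Both comparisons share the controls and the lines KO1 and KO2, so independent draws are no fair reference. With controls 1 and 2 used for one and 3 and 4 for the other, 306 genes were shared and 24 called in opposite directions, or 348 and 16 the other way round. The lines stayed shared there, so differences of the lines from control cannot be told from changes that outlast the rescue. The count of 1050 was 471 without KO_RES 1_2, 673 without KO_RES 1_1, 473 without control 2, 493 without control 1 and 384 with controls 3 and 4 only.

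No gene was called for KO against control and called in the opposite direction for rescue against KO in the 3-group edgeR fit. Its second comparison had 0 calls and 473 genes at an unadjusted p under 0.05, which fixes this count beforehand. The blocked edgeR fits, which do call genes for rescue against KO, were not used for this count. DESeq2 gave 2, ENSG00000117289.7, which has no symbol here, and SYT13. ENSG00000117289.7 had -3.03 for KO against control (adjusted p = 2.22e-08) and 2.36 for rescue against KO (adjusted p = 0.00547). SYT13 had 1.97 (adjusted p = 0.0344) and -3.07 (adjusted p = 0.0328). Across genes, which are not independent replicates, the fold changes of KO against control and of rescue against KO had a correlation of -0.19. Sharing the KO libraries gave -0.491 in simulations without effects, and with KO libraries divided by number the correlation was -0.03 or -0.04. The simulations drew every library independently, whereas KO and rescue libraries share lines and numbers. The simulated -0.491 is therefore no reference for what sharing alone gives here.

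The lines KO1 and KO2 differed widely from each other. APOB, the protein of low-density lipoprotein, was at 10410 and 21600 CPM in the KO1 libraries and at 20.2 and 47.8 CPM in the KO2 libraries (-8.88, adjusted p = 0.000123), against 5902 ± 910 CPM in control. ZNF704 was at 92.8 and 92.2 CPM in KO2 and at 0.0798 and 0.0468 CPM in KO1 (adjusted p = 2.96e-09), and the formin DIAPH2 at 35.7 and 37.2 CPM in KO1 and at 0 and 0.109 CPM in KO2 (adjusted p = 3.37e-06). By the same rule KCNH7, KCNK1, CLMP and TCEAL3 were higher in KO2, and FAM50B, CHODL and IRF5 higher in KO1. The 5-group fit called 2463 genes between the lines, 1286 higher and 1177 lower in KO2. It called 854 without KO 1_1, 1035 without KO 1_2, 1143 without KO 2_1 and 936 without KO 2_2.

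Against control, 3721 genes were called in KO1 (1719 higher, 2002 lower) and 2062 in KO2 (985 higher, 1077 lower). Of these 843 changed in the same direction in both lines, 379 up and 464 down, and 97 in opposite directions, where independent draws would share 82.4 up and 104.9 down. With controls 1 and 2 used for KO1 and 3 and 4 for KO2, 983 genes agreed and 429 were opposite, and 1012 and 567 the other way round. The correlation across genes was 0.41 with shared controls, 0.321 in simulations without effects, and 0.10 and 0.14 with the controls divided. These simulations also drew libraries independently, without the 2 pairs of controls, so 0.321 is no firm reference. The count of 843 was 361 without KO 1_1, 365 without KO 1_2, 225 without KO 2_1, 311 without KO 2_2 and 560 without control 2.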

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

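The tests of explanations, the fit by library number and the splits in this part were chosen after the result they concern was seen, except the test of chromosome medians between controls, while the comparison of the lines was planned; the tests on other cell types and on mislabelled controls replaced first versions that had pointed the other way, and both values are given.

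Controls 1 and 2 differed from controls 3 and 4 more than KO replicates of a line do. In each direction 57 to 75 genes were at least 8-fold apart in the 4 pairs across, and 0 within either pair, which argues against a difference in depth. Libraries of a group from different lines were about as far apart, with 70 and 79 genes for KO 1_1 against KO 2_1. KO_RES 1_2 against KO_RES 2_2 had 50 and 163. RNA of other cell types is argued against by a sum of at most 15.65 CPM for fibroblast, blood and endothelial markers in a control, with LYZ left out. With LYZ the sum was 934.87 CPM, but LYZ was above 268 CPM in every library while PTPRC, CD14 and the hemoglobins stayed under 1 CPM. For KO libraries labelled as control, at least 92 genes lay 8-fold apart between any control and any KO or rescue library, while KO replicates of a line had 0, although a first count of genes on in the controls and off in all others had found only 1. The 92, between control 3 and KO 2_2, counts both directions together. Control 1 against control 3 had 71 and 64 in the separate directions. Controls 3 and 4 thus lay no farther from KO 2_2 (92 and 95) than from controls 1 and 2. Chromosome-wide differences between separately grown populations may contribute: in each pair across, some chromosome had a median log2 difference of at least 0.38, highest on chromosome 13, and none reached 0.25 within pairs. Only 1 or 2 chromosomes per pair across reached 0.25, and the largest median, 0.50, is far below an 8-fold change. The medians alone thus do not account for the 8-fold differences, and how many of those genes lie on such chromosomes was not counted.

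Libraries numbered 2 differed from those numbered 1 in both lines, with 3962 of 19766 genes called in a fit of line, group and number (1942 higher, 2020 lower). In that fit stress response genes were higher (14 of 20 called, median 0.54), and cell cycle genes (18 of 25, -0.51) and NF-kB targets (10 of 13, -0.51) were lower in number 2, with camera adjusted p-values of 0.47, 0.60 and 0.43 with an estimated correlation. Depth is argued against, since number 2 was the deeper library in 2 of the 4 pairs; the genotype field as the true group is argued against, since all 4 libraries titled as rescue had more HKDC1 than all 4 titled as knockout. A hypoxia response may play a part, because 11 of 22 hypoxia genes were higher (median 0.36, camera adjusted p = 5.1e-06), but with an estimated correlation the adjusted p was 0.47, and glycolysis did not pass (0.32), so it cannot be told apart from other culture differences. The differences of number 2 minus 1 correlated across genes at 0.22 to 0.52 with control 4 minus control 3 and at 0.04 to 0.21 with control 2 minus control 1, and no biological explanation other than hypoxia was tested, as the labels do not say what the numbers mean.

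KO1 and KO2 differed at 2463 genes. Chromosome-wide differences as the whole cause are argued against: chromosomes 8, 21 and X, whose median differed by at least 0.3, held 15.6% of the called genes. On chromosome 8, 170 of 694 tested genes were called, 157 of them higher in KO2. On X 177 of 692 were called, 141 of them higher, and on chromosome 21 36 of 230, 33 of them lower. Over all genes 2463 of 20559 were called. Calls also leaned 1 way on chromosomes 3 (168 of 216 lower, median -0.22) and 11 (130 of 163 lower, median -0.16). Such differences may therefore contribute on these 5 chromosomes. A different edit of HKDC1 in the lines stays open and untested.

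The change against control differed between the lines for 12 of 73 named genes, where 2463 of all 20559 genes tested differed. An effect of the knockout cannot be told here from other differences between the lines. KO2 minus KO1 was -4.01 for PAGE5, -3.47 for ARMCX1, -3.75 for PASD1, -1.54 for DPYD, -3.07 for CTTNBP2, -3.62 for CFTR and -2.79 for MGAM, all rising less in KO2. It was 4.77 for ABCA8 and 1.56 for TFPI2, which fell less in KO2, and -1.16 for LIMCH1, -0.84 for CD47 and -1.09 for HKDC1, which were lower in KO2. The direct edgeR test of the difference passed for each. ABCA8 was at 0.0319 and 0 CPM in the KO1 libraries, at or under the floor, so its fitted 4.77 is no exact difference.

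Single libraries stood apart from the other 3 of their group in 9 of 233 groups tested, where chance gives about 11.7. DIO3 was at 11.1 CPM in KO_RES 2_1 (others 0.368 to 1.86), DPYD at 0.453 in control 2 (0.323 to 0.338) and TBX3 at 20.6 in KO 1_1 (10 to 11). TM7SF2 was at 55.2 in KO 2_2 (41.6 to 42.2), HK1 at 28.1 in control 4 (20.4 to 20.9) and CTNNB1 at 462 in KO_RES 2_1 (214 to 243). KO_RES 2_2 had 3 such values: COX6C at 77.5 CPM (105 to 108), BAG3 at 29.3 (24.7 to 25.5) and reads outside annotated genes at 19.53% (13.22 to 14.14).

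Whether chance could give such counts was examined with the 35 splits of 8 libraries into 4 and 4. For KO against control only 1 split, the real one, gave 1206 genes or more, the highest other being 9, and for rescue against control 1 split gave 1050 or more, the highest other being 70. Chance is thereby excluded only if the 8 libraries are taken as exchangeable. They come instead as 2 pairs of controls and 2 lines that stand apart from each other, so chance differences between these 4 units are not excluded. For rescue against KO all 35 splits gave as many as the real 0, which a count of 0 fixes beforehand, so they decide nothing there. The highest other, 5651, parted line 1 from line 2, which points to a structure of the samples by line. For the gene lists 2 splits gave 13 or more for KO against control (highest other 13) and 5 gave 8 or more for rescue against KO (highest other 10), so chance is not excluded. Under the pair block, the 7 other splits that part all 4 pairs gave 0 genes against the real 8; with 8 such splits no share under 0.05 can be reached.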

How the results depend on the processing

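The alternatives that leave out a pair of controls, leave out the 2_2 pair or use DESeq2 with the pair block were chosen after the data were seen. Of the 69 genes named for KO against control, none changed sign in any alternative. They were named because they were called in these libraries, so a stable sign was likely beforehand and is no independent support. All 69 kept their call with RLE, DESeq2 and the 5-group mean. Against controls 3 and 4 only 17 kept it, against controls 1 and 2 only 53, and with only the libraries whose labels agree 11. Depth limits little: at 36075411 to 71853616 counts per library the floor was under 0.0832 CPM, while the spread between libraries of a group left 2-fold changes mostly unrecovered in simulated data (28.4% for KO against control). Where a fit leaves a line or group with 1 library, that library is assumed to vary like the others. The cause of the changes below was not tested, except that stricter thresholds, blocks and fewer libraries act by construction.

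Genes changed for KO against control (1206) became 1883 with groups from the genotype field, 72 with only agreeing libraries, 551 with an absolute log2 fold change of at least 1, 2287 with DESeq2, 3312 with the 5-group mean and 337 with controls 1 and 2 left out. For rescue against control (1050) they became 533 with only the groups compared, 1874 by genotype field, 64 with agreeing libraries, 517 with the fold threshold, 2042 with DESeq2 and 384 with controls 1 and 2 left out. For rescue against KO (0) they became 1 without a filter (HKDC1), 5 with DESeq2, 473 with DESeq2 and the pair block, 3 with the line block, 8 with the pair block and 61 with the pair block without the 2_2 pair. Genes changed in both lines (843) became 1557 without a filter and 1994 with controls 3 and 4 left out. Genes whose rescue effect differs between lines (0) became 192 without a filter and 98 with number as a block, and genes changed back by rescue (0) became 2 with DESeq2.

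Lists past the threshold for KO against control (13) became 6 by genotype field, 8 with the 5-group mean, 0 with an estimated correlation, 4 with fry and 4 with controls 1 and 2 left out. For rescue against KO (8) they became 5 without a filter, 0 with an estimated correlation and 0 with fry. HKDC1 for rescue against KO missed the threshold at 3.15 and passed it at 3.15 without a filter, 3.15 with DESeq2, 3.14 with DESeq2 and the pair block, 3.12 with the line block, 3.15 with the pair block and 2.98 with the pair block without the 2_2 pair.

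Leaving out 1 library at a time, KO against control ran from 509 (without control 2) to 1506, rescue against control from 471 (without KO_RES 1_2) to 1138, and rescue against KO from 0 to 0. Genes changed in both lines ran from 225 to 964, genes that differ between lines from 854 to 2775, genes whose rescue effect differs from 0 to 1, and genes changed back from 0 to 0. Lists ran from 9 to 13 for KO against control and from 2 to 10 for rescue against KO. HKDC1 ran from -0.69 to -0.24 for KO against control and from 2.84 to 3.37 for rescue against KO.

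Signs reversed mainly when groups were taken from the genotype field. HKDC1 for KO against control became 1.69 there, HK1 -0.04 and the cell cycle list 0.05. For rescue against KO, AGR2 became 0.22, CDH2 -0.25, CFTR -0.09, HK1 0.28, HK2 0.53, NECTIN3 -0.37, SLC1A3 0.24 and SYT13 0.04, and the lists became 0.53 (ATF4), -0.09 (cholesterol synthesis), 0.54 (interferon-stimulated), 0.03 (lysosome and mitophagy) and 0.02 (NRF2). With only agreeing libraries HK1 became 0.25, the ATF4 list 0.39 and the interferon-stimulated list 0.12. With controls 1 and 2 left out the cholesterol synthesis list for KO against control became 0.02. With 1 library left out, HK1 for rescue against KO ran from -0.16 to 0.10 (0.06 without KO_RES 1_1, 0.10 without KO 2_2), and NECTIN3 from -0.21 (without KO_RES 2_1) to 0.96.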

Other observations

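The values in this part were chosen after they were seen. SLC19A3, a thiamine transporter, had the smallest adjusted p of the rises for KO against control together with a spread far below its change. It was at 3.17, 3.20, 2.65 and 4.17 CPM in the controls and between 31.2 and 47.3 CPM in the KO libraries (3.51, SE 0.23, adjusted p = 4.25e-05). In the rescue libraries it stayed between 24.2 and 40.5 CPM, above all controls.

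KRT19, a keratin of bile duct cells, was at 0.502 and 0.657 CPM in controls 1 and 2 and at 38.5 and 34.2 CPM in controls 3 and 4. It was at 8.86 and 7.05 CPM in KO1 and at 229 and 194 CPM in KO2. AFP, the fetal albumin relative used as a liver cancer marker, was at 8.13, 7.30, 19.6 and 15.8 CPM in the KO libraries and higher in each paired rescue library, at 31.0, 74.7, 52.0 and 27.4 CPM. The pair block gave AFP a log2 fold change of 1.84 for rescue against KO (adjusted p = 0.136). AFP passed in 2 of 25 alternatives, chosen after the data were seen: DESeq2 with the pair block (1.85, adjusted p = 0.0189) and the pair block without the 2_2 pair (2.20).

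Between libraries numbered 2 and 1, the serine dehydratase SDS was higher in number 2 (1.92, SE 0.12, adjusted p = 1.9e-05), as were the histidine ammonia-lyase HAL (1.76, adjusted p = 1.9e-05) and the tyrosine aminotransferase TAT (1.07, adjusted p = 0.000569). THBS1 (-1.29, adjusted p = 0.000179), CXCL1 (-1.44, adjusted p = 0.000297) and EDN1 (-1.65, adjusted p = 0.000646) were lower. With the number in the fit, 531 genes were called for rescue against KO, 158 higher and 373 lower.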
